A study of Mus musculus with 26 samples.

How the data were processed

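The 26 arrays measured RNA of blood stem and progenitor cells sorted from the bone marrow of Gata1-EGFP reporter mice. Per the labels, the mice were 8 to 15 weeks old, RNA was extracted with RNeasy Micro, and biotin-labelled cRNA was hybridised to Mouse Gene 1.1 ST arrays. The deposited values are log2 signals, 1 per probe set and array. The submitters' processing notes name robust multi-array averaging (RMA) and oligo, without versions, steps or the base of the logarithm. The range of the values fits base 2, the base that RMA uses, and it is taken here. No raw intensities were used. Array medians lay between 6.4 and 6.7. The median of all values, 6.61, was used as the level under which a gene is said to be below the median signal. Signals under it were not shown to exceed background. A log2 difference from a mean under it is one of signal, may not equal that of the RNA, and is not converted to a fold; the report names the genes this concerns.

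Of 35556 probe sets, 21789 named 1 gene, 1621 named several and 12146 had no gene name in the annotation used, which is that of the 1.0 ST version of the array. Probe sets of several genes and of none were left out. Of the rest, 21698 were matched to an Entrez record and 0 symbols changed. For the 999 genes with several probe sets the one with the highest mean over all arrays was taken, leaving 19938 genes. A gene with close relatives may share probes with them.

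A linear model was fitted to all 26 arrays with 1 coefficient for each of the 8 groups in limma 3.58.1 under R 4.3.3, so that all groups share 1 estimate of spread. Contrasts were tested with moderated t-tests and adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were reporter-positive against reporter-negative cells in PreGM and in GMP, the difference between these effects, GMP against PreGM in reporter-negative and in reporter-positive cells, PreMegE against PreGM GFP+, PreGM GFP- against LMPP, LMPP against HSC GFP- and CLP against LMPP, with a moderated F test over all groups. The groups, the tests, the gene lists and the alternative analyses were chosen before the data were examined, from the labels and general knowledge. A later set of alternatives, chosen after seeing the data, used the mean of Y-linked genes as a covariate, the first component of the residuals as a covariate, or left out the array with the widest residuals in each of PreGM GFP-, PreMegE and HSC GFP- (arrays 2, 1 and 1).

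The lists held genes of erythroid cells (21 measured), heme synthesis (11), megakaryocytes (20), mast cells and basophils (24), eosinophils (14), neutrophil granules (27), monocytes and macrophages (22), dendritic cells (17), B lymphoid cells (22), T and NK lymphoid cells (22), lymphoid priming (21), stem cells (28), G2 and M phase (24), S phase and DNA replication (28), interferon response (21), immediate early and stress response (23), stroma and endothelium (19) and fate regulators (35). Each was tested with camera at a preset correlation of 0.01 between genes, and its p adjusted over the lists of the comparison; this was repeated with the correlation estimated from the data and with fry. Counts of list genes are given over the adjustment for all genes and, for many but not all lists, after it adjusted over the list alone. Sort markers (11 measured) and sex-linked genes (4) served as checks and were not tested as lists. Markers for the closing tests were chosen after the results were seen, and the chance splits were set out before they were run.

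Genes are named by rule. In the reporter comparisons these are the 12 genes with the largest rise and the 12 with the largest fall among the called genes in which each array of 1 group lies above each array of the other. Elsewhere they are the 6 each way, or all where fewer qualified. For the difference between the reporter effects the overlap of arrays was not considered. Symbols that are only model or clone identifiers, small RNAs, olfactory and vomeronasal receptors and antigen receptor segments were passed over. At most 4 examples are given per list, from the called genes with the largest differences. Gata1, fate regulators and sort markers may be named in any comparison. Xist, S100a8, S100a9, Mpo, Elane, Ctsg, Ms4a3 and Cx3cr1, where named outside these rules, were chosen after their values were seen. Log2 differences are of the first-named group minus the other, and group values are means with the SD of arrays. The analysis was tested on simulated values built from the residual spread, with 200 genes changed. Of genes changed by 1 log2 unit 70.2% were recovered in the PreGM and 74.6% in the GMP reporter comparison, with 3.08% and 7.95% of calls false. Each simulated gene had the same spread in all arrays, so these shares do not allow for groups of wider spread, such as PreGM GFP-. On unchanged simulated values 0 of 360 list tests passed, but these values were drawn independently for each gene. They cannot show how the list tests behave where genes of a list vary together. In the data the estimated correlation was 0.494 for G2 and M phase genes and 0.205 for monocyte and macrophage genes. Alternatives used arrays centred on their medians, cyclic loess, array weights, an intensity trend with a robust prior, the groups compared alone, the replicate number as a block, each probe set, the mean of probe sets, a 2-fold threshold, genes above the median level and each array left out in turn.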

Results

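The series measured gene expression in blood stem and progenitor cells sorted from the bone marrow of mice that carry an enhanced green fluorescent protein (GFP) reporter of Gata1, the transcription factor of erythroid, megakaryocyte, mast cell and eosinophil development. The 26 arrays fall into 8 sorted populations. There were 3 arrays each of haematopoietic stem cells without reporter signal (HSC GFP-), common lymphoid progenitors (CLP), pre-granulocyte-macrophage progenitors without and with reporter signal (PreGM GFP- and PreGM GFP+), granulocyte-macrophage progenitors with reporter signal (GMP GFP+) and pre-megakaryocyte-erythroid progenitors (PreMegE). Lymphoid-primed multipotent progenitors (LMPP) and GMP without reporter signal (GMP GFP-) had 4 arrays each. Reporter-positive HSC are named in the description of the series and are not analysed here. Each array gives 1 log2 signal per probe set, array medians lay between 6.4 and 6.7, and the number of arrays per group limits the precision. The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

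Gata1 itself followed the reporter labels. Its log2 signal was 8.48 ± 0.41 (SD, n = 3) in PreGM GFP+, 8.08 ± 0.15 (SD, n = 3) in GMP GFP+ and 8.47 ± 0.32 (SD, n = 3) in PreMegE. In PreGM GFP- it was 6.74 ± 0.39 (SD, n = 3), in GMP GFP- 6.42 ± 0.04 (SD, n = 4), in LMPP 6.57 ± 0.09 (SD, n = 4), in CLP 6.41 ± 0.16 (SD, n = 3) and in HSC GFP- 6.31 ± 0.09 (SD, n = 3). Transcripts of the sorting antigens mostly followed the gates. Fcgr3, which encodes an Fc gamma receptor recognised by the GMP gate, was 9.52 ± 0.51 (SD, n = 4) in GMP GFP- and 9.78 ± 0.56 (SD, n = 3) in GMP GFP+, against 7.49 ± 0.08 (SD, n = 3) in PreGM GFP-. Slamf1, which encodes CD150, was 7.17 ± 0.78 (SD, n = 3) in PreMegE and 7.15 ± 0.26 (SD, n = 3) in HSC GFP-, against 4.91 ± 0.21 (SD, n = 4) in LMPP. Below the median signal, it was also higher in PreGM GFP+ than in PreGM GFP- by 0.98 (SE 0.25, adjusted p = 0.0427), at 5.84 against 4.87. Flt3 was 11.44 ± 0.24 (SD, n = 4) in LMPP, and Il7r was 9.94 ± 0.36 (SD, n = 3) in CLP. Over all 8 groups, 3036 of 19938 genes differed by the moderated F test of limma. Within groups, arrays correlated with r between 0.950 and 0.989 over all genes, and between groups with r between 0.923 and 0.983.

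**Figure D1:**
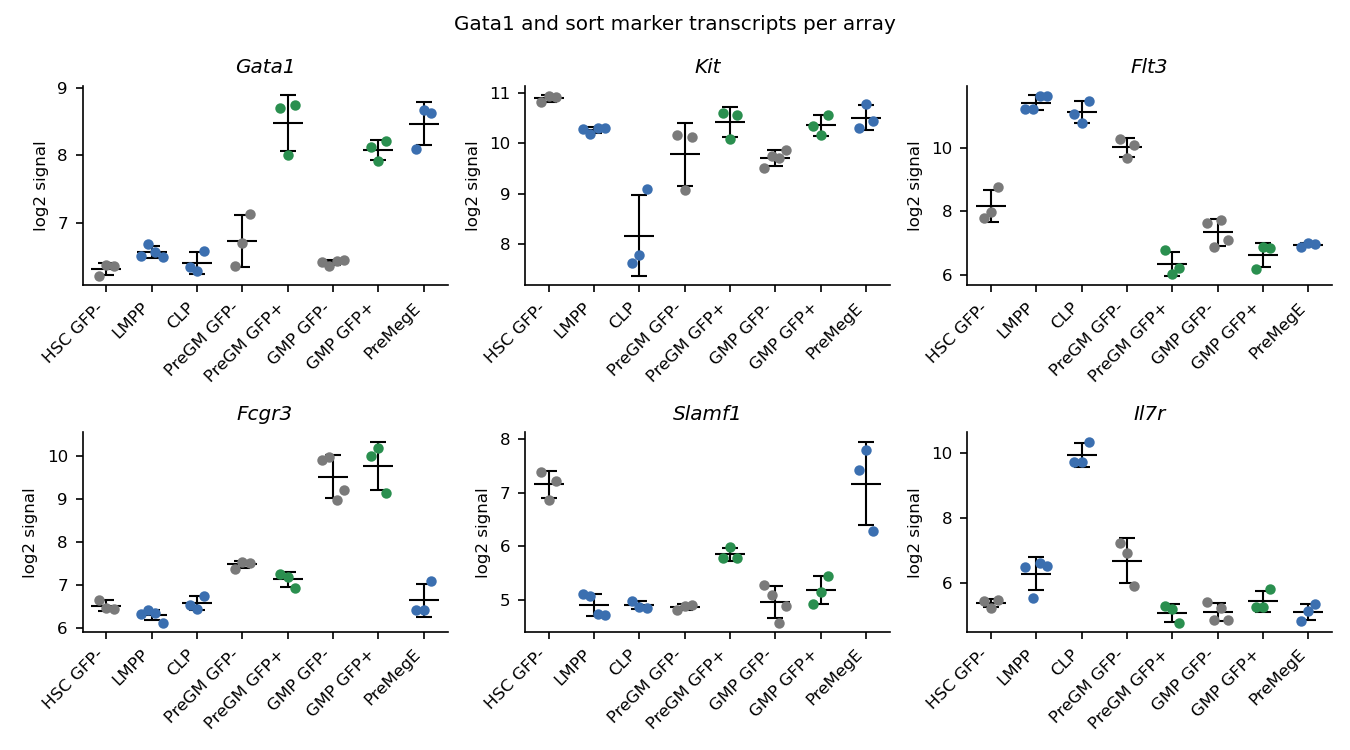
Log2 signal (vertical axis) of Gata1 and 5 transcripts of sorting antigens in each array (points) of the 8 sorted populations (horizontal axis), with the group mean and SD (black bars, n = 3, or 4 for LMPP and GMP GFP-). Gata1 averaged 8.48, 8.08 and 8.47 in PreGM GFP+, GMP GFP+ and PreMegE, and at most 6.74 in the other 5 groups.

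The PreGM comparison asks how cells of 1 surface gate (lineage-negative, Kit-positive, Sca1-negative, without the Fc gamma receptor, CD150 and CD105) differ by reporter activity. Gata1 was higher in PreGM GFP+ than in PreGM GFP- by 1.75 (SE 0.19, adjusted p = 2.36e-06) on the log2 scale. The largest rises in signal were those of Car1, a carbonic anhydrase of early erythroid cells, by 5.54 (SE 0.33, adjusted p = 1.68e-10) and of the sodium pump subunit gene Atp1b2, by 3.95 (SE 0.20, adjusted p = 1.65e-11). Ms4a2 and Fcer1a, which encode chains of the high-affinity IgE receptor of mast cells and basophils, rose by 3.72 and 3.45. The largest falls in signal were those of the myeloid membrane protein gene Ms4a6c, by 5.18 (SE 0.61, adjusted p = 1.04e-05), and of Dntt, the terminal deoxynucleotidyl transferase of lymphoid cells, by 4.62 (SE 0.21, adjusted p = 2.00e-12). The cytokine receptor gene Flt3 fell by 3.68 (SE 0.27, adjusted p = 1.00e-08). In all, limma called 181 genes higher and 227 lower in PreGM GFP+ (Benjamini-Hochberg adjusted p under 0.05), 112 and 155 of them by at least 2-fold. The other most raised genes were Cd55, the lipid transporter gene Mfsd2b, Scin, Prkch, the melanocortin receptor gene Mc2r, the aquaporin gene Aqp9, Ces2g and Gstm5, with rises from 3.0 to 3.84. The other most lowered genes were the monocyte genes Ly86, F13a1, Mpeg1 and Ctss with Emb, Milr1, Clec12a, Cd53 and Gria3, with falls from 3.09 to 4.29. In PreGM GFP- the means of Aqp9, Car1, Cd55, Ces2g, Fcer1a, Gzmb, Klf1, Mc2r, Ms4a2, Prkch and Scin, and in PreGM GFP+ those of Clec12a, Dntt, F13a1, Flt3, H2-Aa, Hp, Id2, Ly86, Milr1, Mpeg1 and Ms4a6c, lay below the median signal, so these differences are not exact.

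Erythroid genes rose together in PreGM GFP+: 11 of 21 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 1.28e-31), among them Mfsd2b by 3.61, the water channel gene Aqp1 by 2.37 and Icam4 by 1.88. Megakaryocyte genes were higher as a group (4 of 20 rose and 0 fell, 6 and 0 adjusted over the list alone, camera adjusted p = 2.44e-06), led by the thrombin receptor gene F2r at 1.75 and the platelet glycoprotein genes Gp5 at 1.53 and Itga2b at 1.13. In the mast cell and basophil list 7 of 24 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 2.29e-08), including the monoamine transporter gene Slc18a2 at 1.63 and Gzmb at 1.39. Of 14 eosinophil genes 1 rose, Siglecf by 0.55, and the list did not pass the test (1 and 0 adjusted over the list alone, camera adjusted p = 0.312). Heme synthesis genes passed it as a list (median 0.26, camera adjusted p = 0.0138) with 0 of 11 called (1 and 0 adjusted over the list alone). That call was lost without PreGM GFP- array 2 (adjusted p = 0.0820) and without PreGM GFP+ array 2 (adjusted p = 0.0714).

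Genes of neutrophils, monocytes and lymphoid cells fell in PreGM GFP+. Of 27 neutrophil granule genes 8 fell and 0 rose (0 and 9 adjusted over the list alone, camera adjusted p = 1.72e-15), with the primary granule protease genes Ctsg at -2.78, Elane at -2.26 and Prtn3 at -1.99, and Hp at -2.46. The late neutrophil gene S100a8 was 8.66 ± 1.64 (SD, n = 3) in PreGM GFP+ and 8.97 ± 0.86 (SD, n = 3) in PreGM GFP-, and was not called. Of 22 monocyte and macrophage genes 10 fell and 0 rose (0 and 14 adjusted over the list alone, camera adjusted p = 7.31e-29), including Ly86 at -4.29, F13a1 at -3.94 and Mpeg1 at -3.16. Of 21 lymphoid priming genes 9 fell and 1, Bcl11a, rose (1 and 11 adjusted over the list alone, camera adjusted p = 2.78e-16); the genome organiser gene Satb1 fell by 2.47. Dendritic cell genes fell in 4 of 17 with 0 raised (0 and 4 adjusted over the list alone, camera adjusted p = 2.65e-05). B lymphoid genes fell in 3 of 22 with 0 raised (0 and 5 adjusted over the list alone, camera adjusted p = 2.08e-10). PreGM GFP- array 3 carried least of both falls. As mean deviations from each gene's overall mean, arrays 1 to 3 had 0.48, 0.31 and 0.09 for dendritic and 0.41, 0.55 and 0.01 for B lymphoid genes. PreGM GFP+ arrays had at most -0.29 and -0.31. T and NK lymphoid genes fell in 2 of 22 with 0 raised (0 and 4 adjusted over the list alone, camera adjusted p = 0.00168). This fall rests on PreGM GFP- arrays 1 and 2. The mean deviations of these genes were 0.37, 0.19 and -0.03 in PreGM GFP- arrays 1 to 3, and -0.03, -0.14 and -0.05 in PreGM GFP+. The antigen presentation gene H2-Aa fell by 3.02. All of these list calls in PreGM, erythroid to lymphoid, held with an estimated correlation, the weakest being T and NK lymphoid (adjusted p = 0.0352 with an estimated correlation).

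Among 35 fate regulators 6 rose and 3 fell in PreGM GFP+ (11 and 9 adjusted over the list alone, camera adjusted p = 0.202). Gata2, a partner of Gata1 in early progenitors, rose by 1.80, the erythroid factor gene Klf1 by 1.25, Gfi1b by 1.10 and the Gata1 cofactor gene Zfpm1 by 0.87. Irf8, a monocyte and dendritic cell factor, fell by 1.95 and Id2 by 2.08. Spi1 differed by -1.13 (adjusted p = 0.0801) and Cebpa by -0.74 (adjusted p = 0.0651). Of 28 stem cell genes 2 rose and 2 fell (5 and 2 adjusted over the list alone), and the list call (camera adjusted p = 0.0306) was lost with an estimated correlation (adjusted p = 0.0872). Cell cycle lists were lower in PreGM GFP+ with 0 of their genes called. For S phase and DNA replication the median was -0.25 over 28 genes (0 and 0 adjusted over the list alone, camera adjusted p = 3.02e-08, adjusted p = 0.0337 with an estimated correlation). For G2 and M phase it was -0.43 over 24 genes (0 and 0 adjusted over the list alone, camera adjusted p = 3.70e-08), a call lost with an estimated correlation (adjusted p = 0.127). Interferon response genes had 0 of 21 called (0 and 0 adjusted over the list alone, camera adjusted p = 0.0371, adjusted p = 0.187 with an estimated correlation). Immediate early and stress genes (0 of 23 called, 0 and 0 adjusted over the list alone, camera adjusted p = 0.50) and stroma and endothelium genes (0 of 19 called, 0 and 0 adjusted over the list alone, camera adjusted p = 0.638) did not pass.

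Single arrays moved these counts in PreGM. Without PreGM GFP+ array 3, 118 genes were higher, and without PreGM GFP- array 1 or PreGM GFP+ array 1, 134 or 146 were lower. With the spread taken from the 6 PreGM arrays alone, 89 genes were higher and 128 lower, and with arrays weighted by precision 93 and 120. Prkch, at 3.49 (adjusted p = 0.0462), was the least secure of the genes named for PreGM: its call was lost without any of 5 of the 6 arrays (adjusted p up to 0.253 without PreGM GFP- array 1), and its difference was 2.20 as the mean of its 2 probe sets.

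The GMP comparison puts the same question to the gate with the Fc gamma receptor. Gata1 was higher in GMP GFP+ than in GMP GFP- by 1.67 (SE 0.17, adjusted p = 8.58e-07). The IgE receptor gene Fcer1a rose by 6.30 (SE 0.37, adjusted p = 7.09e-11) and Prg2, the eosinophil major basic protein gene, by 6.25 (SE 0.46, adjusted p = 2.53e-09) to 12.60 ± 0.44 (SD, n = 3). The granzyme gene Gzmb rose by 5.56 (SE 0.26, adjusted p = 2.49e-12) and Car1 by 4.65 (SE 0.30, adjusted p = 4.04e-10). The clotting factor gene F13a1 of monocytes fell by 4.04 (SE 0.39, adjusted p = 2.01e-07) and the granule protein gene Hp by 3.75 (SE 0.28, adjusted p = 3.01e-09). Limma called 642 genes higher and 807 lower in GMP GFP+, 204 and 268 of them by at least 2-fold. The other most raised genes were Ms4a2, the eosinophil granule genes Ear6 and Prg3, Rnase12, Scin, Slc18a2, Il6 and the mast cell carboxypeptidase gene Cpa3, with rises from 3.53 to 5.37. Ear6 belongs to a family of closely related genes, and its probe set may read other members. The other most lowered genes were Mgst2, Chil3, Tfec, Ltf, Elane, Ifi209, Ly86, Clec5a, Camp and Ly6a2, with falls from 2.87 to 3.72. In GMP GFP- the means of Car1, Cldn13, Ear6, Epx, Fcer1a, Gata1, Gzmb, Il6, Mitf, Ms4a2, Prg2, Rnase12, Scin and Slc18a2, and in GMP GFP+ those of Clec5a, Ifi209, Ly6a2 and Mpeg1, lay below the median signal, so these differences are not exact.

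Mast cell and basophil genes were raised in GMP GFP+ in 18 of 24 with 0 lowered (22 and 0 adjusted over the list alone, camera adjusted p = 3.49e-32). Beside Fcer1a, Gzmb and Ms4a2 they included Slc18a2 at 3.96. Eosinophil genes were raised in 8 of 14 with 0 lowered (10 and 0 adjusted over the list alone, camera adjusted p = 4.24e-14), with Prg3 at 4.32 and the eosinophil peroxidase gene Epx at 3.34. Erythroid genes were raised in 14 of 21 with 0 lowered (17 and 1 adjusted over the list alone, camera adjusted p = 4.13e-12), with Car2 at 2.20, Icam4 at 1.96 and Cldn13 at 1.63. These 3 calls held with an estimated correlation, the weakest being erythroid (adjusted p = 0.00171 with an estimated correlation). Megakaryocyte genes rose in 4 of 20 and fell in 0 (5 and 0 adjusted over the list alone), led by Itga2b at 1.44; the list call (camera adjusted p = 0.0121) was lost with an estimated correlation (adjusted p = 0.0716). Heme synthesis genes had 0 of 11 called (camera adjusted p = 0.919).

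Neutrophil granule genes fell in 16 of 27 in GMP GFP+ and rose in 0 (0 and 20 adjusted over the list alone, camera adjusted p = 5.45e-28), including Chil3 by 3.48, the lactoferrin gene Ltf by 3.09 and Elane by 3.09, while Mpo differed by -0.48 without a call. Monocyte and macrophage genes fell in 13 of 22 (1 and 15 adjusted over the list alone, camera adjusted p = 1.04e-15), with Ly86 at -3.04, the NADPH oxidase gene Cybb at -2.84 and Mpeg1 at -2.30, and 1 gene, Cx3cr1, rose by 1.25. S phase genes fell in 12 of 28 with 0 raised (0 and 23 adjusted over the list alone, camera adjusted p = 8.47e-19), among them the ribonucleotide reductase gene Rrm2 at -1.17 and the replicative helicase gene Mcm3 at -1.12. These 3 calls held with an estimated correlation, the weakest being monocyte and macrophage (adjusted p = 0.0030 with an estimated correlation). G2 and M phase genes fell in 7 of 24 with 0 raised (0 and 18 adjusted over the list alone), led by Bub1b at -0.93, but their list call (camera adjusted p = 5.00e-13) was lost with an estimated correlation (adjusted p = 0.0716). Lymphoid priming genes (2 of 21 higher, 3 lower, camera adjusted p = 0.10) and B lymphoid genes (0 of 22 higher, 1 lower, camera adjusted p = 0.919) did not pass the list test. Nor did T and NK lymphoid genes (0 of 22 called, camera adjusted p = 0.251) or dendritic cell genes (1 of 17 higher, 0 lower, camera adjusted p = 0.588). The same held for stem cell genes (3 of 28 higher, 0 lower, camera adjusted p = 0.0561) and interferon response genes (3 of 21 higher, 1 lower, camera adjusted p = 0.0931). Immediate early and stress genes (1 of 23 higher, 1 lower, camera adjusted p = 0.119) and stroma and endothelium genes (1 of 19 higher, 1 lower, camera adjusted p = 0.641) did not pass either.

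Fate regulators split in both directions in GMP GFP+: 13 of 35 rose and 6 fell (14 and 8 adjusted over the list alone), and their list call (camera adjusted p = 0.0169) was lost with an estimated correlation (adjusted p = 0.131). Id2 rose by 2.90, Ikzf2 by 2.84, Lmo4 by 2.64, Gata2 by 2.36, the mast cell factor gene Mitf by 0.83 and Runx1 by 1.06. Irf8 fell by 2.05, Spi1, the myeloid factor PU.1, by 1.12, and Myc by 0.85. Cebpa differed by -0.08 (adjusted p = 0.841). Among the sex-linked check genes Xist was higher in GMP GFP+ by 0.95 (adjusted p = 0.00326), with 11.21 ± 0.20 (SD, n = 3) against 10.26 ± 0.22 (SD, n = 4). Without GMP GFP+ array 3 the count of higher genes was 320, and without GMP GFP- array 2 the counts were 424 higher and 529 lower; 489 were lower without GMP GFP+ array 1. With each array centred on its median the split was 432 higher and 1054 lower, or 29.1% higher against 44.3%, and with arrays weighted by precision 1249 and 1550.

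**Figure D2:**
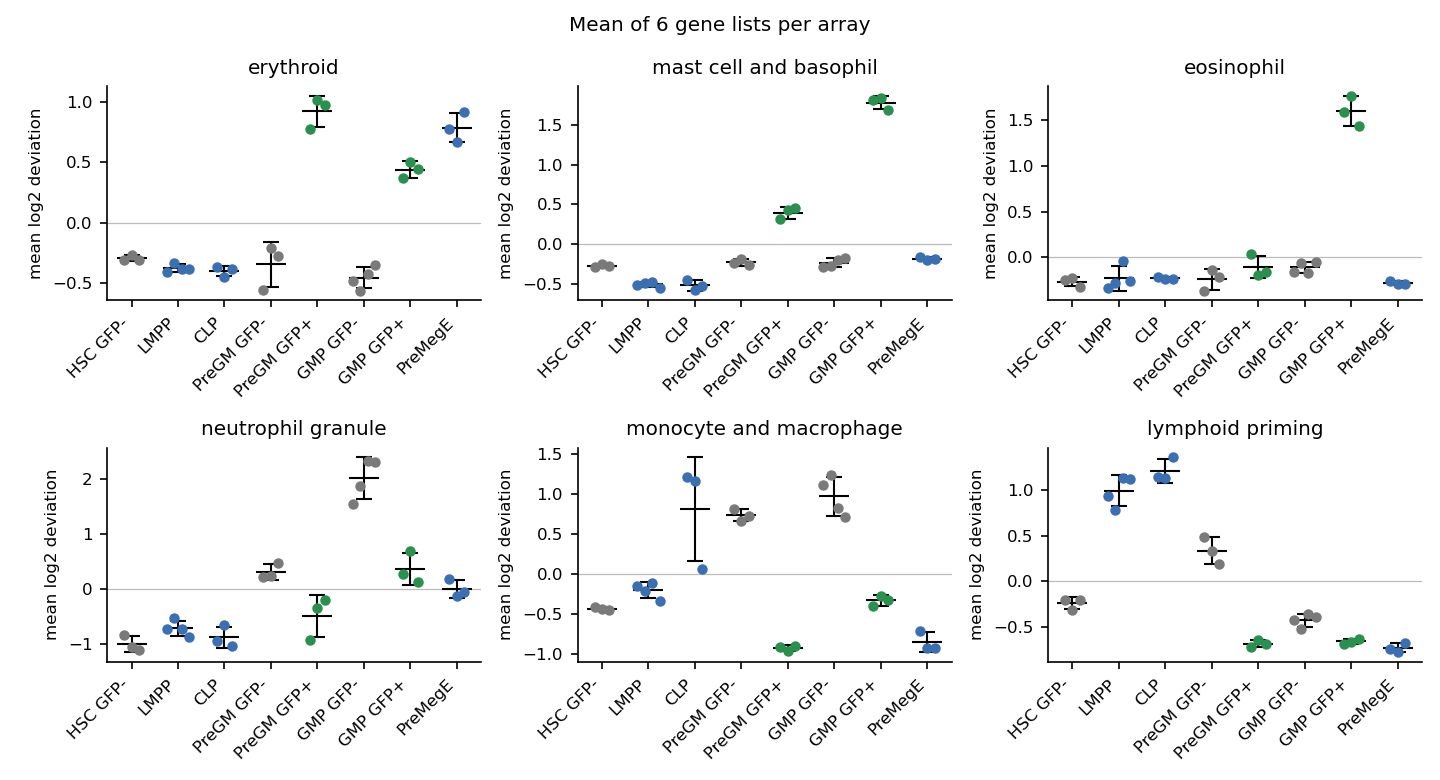
Mean deviation (log2, vertical axis) of the members of 6 gene lists from each gene's mean over all 26 arrays, per array (points) and sorted population (horizontal axis), with the group mean and SD (black bars, n = 3, or 4 for LMPP and GMP GFP-). The erythroid mean was 0.92 in PreGM GFP+, 0.44 in GMP GFP+ and 0.79 in PreMegE, the mast cell and basophil mean 0.40, 1.78 and -0.18, and the eosinophil mean -0.11, 1.60 and -0.28.

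The reporter effects of PreGM and GMP, which share no array, overlapped. Of the genes higher with the reporter, 104 were called in both gates where independent lists would share 5.83, and of the lower genes 125 where independent lists would share 9.19. Opposite calls were 1 gene higher in PreGM and lower in GMP and 2 genes the other way. Car1, Ms4a2, Fcer1a and Gata2 rose in both gates, and Ly86, F13a1, Irf8 and Elane fell in both. Across all 19938 genes the effects correlated with Pearson's r = 0.51 and Spearman's rho = 0.38, and among the 1625 genes called in either gate 87.2% had the same sign. Genes are not independent replicates, so these values describe the effects and carry no p.

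A test of the difference itself called 140 genes: for 37 the reporter effect in PreGM minus that in GMP was positive, and for 103 it was negative. Prg2 differed most, by 5.25 (SE 0.67, adjusted p = 6.79e-05) towards GMP, followed by Id2, which fell in PreGM and rose in GMP (difference -4.98, adjusted p = 3.97e-06), and Ear6 (-4.95). Dntt (-4.50) and Ms4a6c (-4.22) fell with the reporter in PreGM and were not called in GMP, where Dntt, at 5.64 in GMP GFP- and below the median signal, had little room to fall. Mcpt8 (-4.22), a basophil protease gene, rose in GMP. In the other direction stood Camp (3.08), Chil3 (2.76), Mfsd2b (2.64), Ly6a2 (2.51), Clec4a2 (2.44) and Stom (2.32). By class, 74 of the 140 genes were called higher in GMP, 28 lower in GMP, 26 lower in PreGM and 9 higher in PreGM, each with a smaller or opposite effect in the other gate, and 3 were called in neither. The effects on the mast cell and basophil list (11 of 24 genes larger in GMP, camera adjusted p = 3.86e-29) and the eosinophil list (5 of 14, camera adjusted p = 5.05e-18) were larger in GMP. The effects on lymphoid priming genes (4 of 21, camera adjusted p = 6.17e-07) and B lymphoid genes (2 of 22, camera adjusted p = 3.40e-08) were lower in PreGM. So were those on dendritic cell genes (3 of 17, camera adjusted p = 4.90e-05) and on T and NK lymphoid genes with 0 of 22 called (camera adjusted p = 1.18e-04). The mean effects on these 4 lists were -1.02, -0.67, -0.60 and -0.25 in PreGM, against -0.23, 0.07, 0.22 and 0.13 in GMP, where camera called none of them. In GMP GFP- the lists already averaged -0.43, -0.42, -0.29 and -0.13 as deviations from each gene's overall mean, against -0.68, -0.34, -0.31 and -0.08 in PreGM GFP+, so all but lymphoid priming may have had little room to fall there. Erythroid genes as a list rose slightly more in PreGM (2 of 21, median 0.10, mean 0.37, camera adjusted p = 2.36e-05). Yet 14 of the 21 were called higher by reporter in GMP and 11 in PreGM. Neutrophil granule genes as a list fell more in GMP (3 of 27, camera adjusted p = 9.87e-09). Adjusted over the list alone, the effect was lower in GMP for 10 neutrophil granule genes and lower in PreGM for 2. Mpo and Ctsg went against the list, and Ms4a3 did so slightly. Mpo means went from 13 to 11.37 by reporter in PreGM and from 13.36 to 12.88 in GMP. Ctsg means went from 11.37 to 8.59 in PreGM and from 12.07 to 11.34 in GMP. These 8 list calls held with an estimated correlation, the weakest being dendritic cell (adjusted p = 0.0470 with an estimated correlation). The heme synthesis (camera adjusted p = 0.0403, adjusted p = 0.0588 with an estimated correlation) and G2 and M phase (camera adjusted p = 0.00304, adjusted p = 0.430 with an estimated correlation) lists lost their calls. So did the S phase (camera adjusted p = 1.04e-06, adjusted p = 0.0588 with an estimated correlation) and immediate early and stress lists (camera adjusted p = 0.0216, adjusted p = 0.321 with an estimated correlation). Without PreGM GFP- array 1 the positive count was 59, and without PreGM GFP+ array 2 the negative count was 67. The calls of Camp and Chil3 were lost without 7 and 9 of the 13 arrays in turn (adjusted p up to 0.0888 for Camp without GMP GFP+ array 1 and 0.150 for Chil3 without PreGM GFP+ array 3), and that of Ms4a6c without PreGM GFP+ array 2 (adjusted p = 0.0516).

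**Figure D3:**
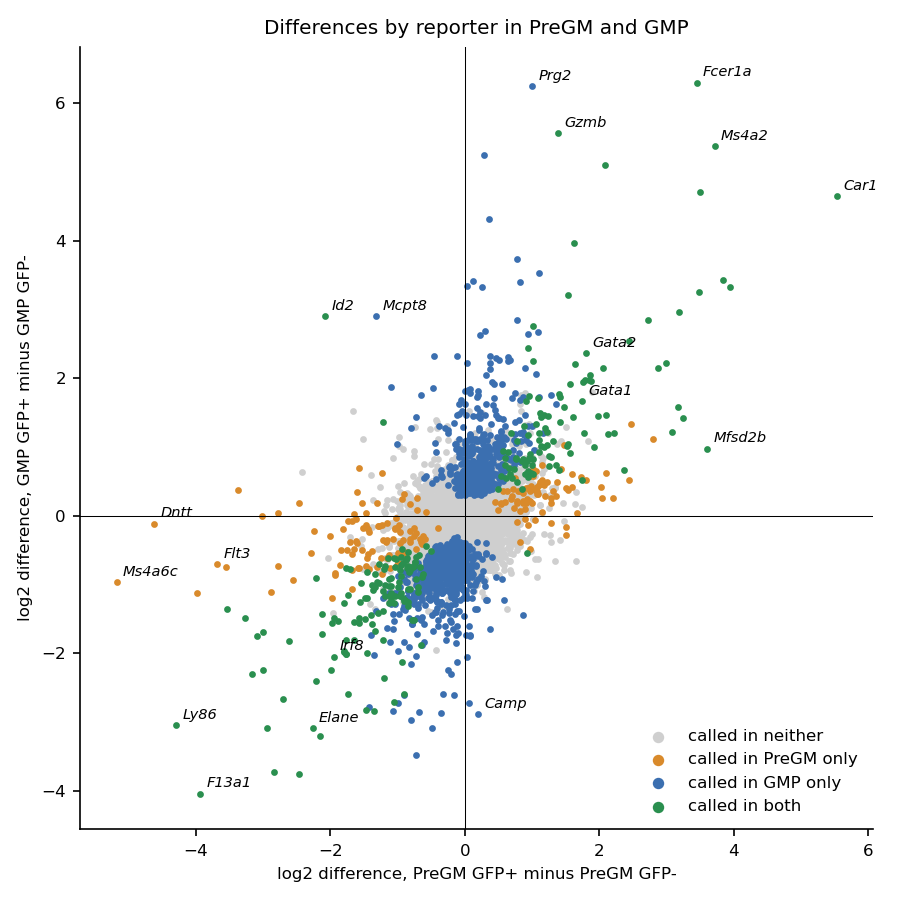
Log2 difference by reporter in GMP (vertical axis, GMP GFP+ minus GMP GFP-) against that in PreGM (horizontal axis, PreGM GFP+ minus PreGM GFP-) for 19938 genes (points), coloured by the comparisons in which limma called the gene. Car1 (5.54 and 4.65) and Ly86 (-4.29 and -3.04) moved alike in both gates, Prg2 differed by -5.25 (PreGM minus GMP), and Id2 fell in PreGM (-2.08) and rose in GMP (2.90).

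PreMegE cells, which carry CD150, were set against PreGM GFP+ cells, the reporter-positive fraction of the gate without it. Gata1 did not differ detectably (-0.01, 95% interval -0.40 to 0.38, adjusted p = 1.0). In PreMegE the IgE receptor gene Ms4a2 was lower by 3.23 (SE 0.28, adjusted p = 1.91e-06), the histidine decarboxylase gene Hdc by 1.75 (SE 0.17, adjusted p = 1.17e-05) and Mpo, the myeloperoxidase gene, by 1.91 (SE 0.25, adjusted p = 9.93e-04). The fate regulator gene Lmo4 was lower by 1.96 (SE 0.28, adjusted p = 0.00290), Fcer1a by 2.14 (SE 0.40, adjusted p = 0.0442) and Atp8b4 by 1.97 (SE 0.31, adjusted p = 0.00839). The 3 genes called higher were Chil3, by 2.52 (SE 0.47, adjusted p = 0.0442), Slamf1, the CD150 gene of the gate itself, by 1.32 (SE 0.25, adjusted p = 0.0442), and F2r by 0.90 (SE 0.16, adjusted p = 0.0234). Limma called only these 3 genes higher and 10 lower at an adjusted p under 0.05. An unadjusted p under 0.05 was found for 764 of 19938 genes, a share below the 0.05 that would occur without any difference. Mast cell and basophil genes fell in 3 of 24 with 0 raised (0 and 7 adjusted over the list alone, camera adjusted p = 5.47e-12, adjusted p = 3.74e-06 with an estimated correlation). In PreGM GFP+ the means of Chil3 and Slamf1, and in PreMegE those of Atp8b4, Fcer1a, Hdc and Ms4a2, lay below the median signal, so these differences are not exact.

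Several smaller list shifts in PreMegE were lost with an estimated correlation. Neutrophil granule genes moved both ways (1 of 27 higher, 1 lower, 8 and 3 adjusted over the list alone, camera adjusted p = 0.00342, adjusted p = 0.347 with an estimated correlation). The late neutrophil gene S100a8 was 10.86 ± 0.60 (SD, n = 3) in PreMegE and 8.66 ± 1.64 (SD, n = 3) in PreGM GFP+, while Elane was 6.77 ± 0.06 (SD, n = 3) and 6.62 ± 0.32 (SD, n = 3). Erythroid genes had 0 of 21 called (median -0.09, camera adjusted p = 0.0262, adjusted p = 0.347 with an estimated correlation) and megakaryocyte genes 1 of 20 (camera adjusted p = 0.0453, adjusted p = 0.347 with an estimated correlation). S phase genes (0 of 28 called, camera adjusted p = 0.00664, adjusted p = 0.35 with an estimated correlation) and stroma and endothelium genes (0 of 19 called, camera adjusted p = 0.0176, adjusted p = 0.347 with an estimated correlation) were alike in this. With the spread taken from these 6 arrays alone 0 genes were called either way. The count of 3 higher genes was 0 without PreGM GFP+ array 1, PreGM GFP+ array 2 or PreMegE array 2 and 1 without PreGM GFP+ array 3. The calls of Chil3, Slamf1 and F2r were each lost without 5 of the 6 arrays in turn, among them PreMegE array 1 (adjusted p = 0.154, 0.332 and 0.129). The lower genes were 6 without PreGM GFP+ array 3 and 5 without PreMegE array 1. With each array centred on its median the split was 1 higher and 7 lower, or 12.5% higher against 23.1%, and with cyclic loess 0 and 8. The calls of Fcer1a and Atp8b4 were also lost without single arrays (adjusted p up to 0.322 for Fcer1a without PreGM GFP+ array 2 and 0.106 for Atp8b4 without PreGM GFP+ array 3).

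**Figure D4:**
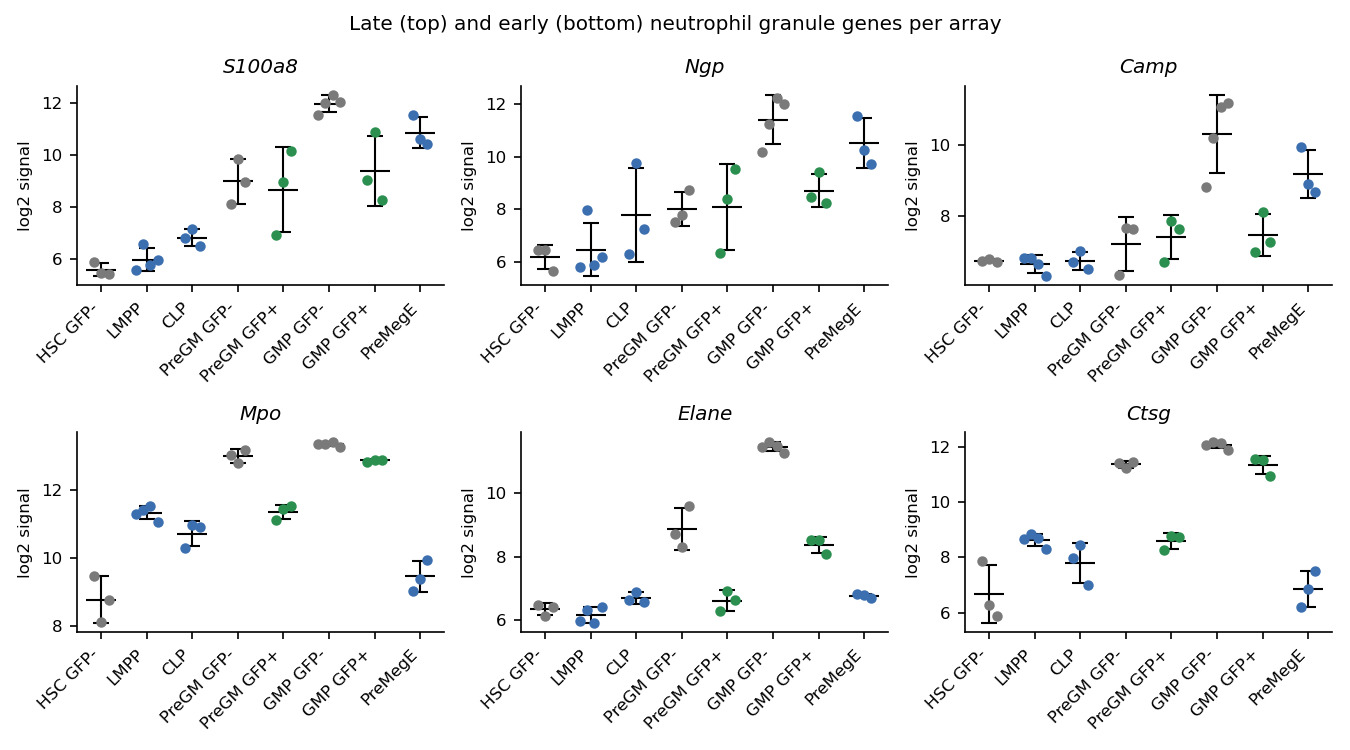
Log2 signal (vertical axis) of 3 late and 3 early neutrophil genes in each array (points) of the 8 sorted populations (horizontal axis), with the group mean and SD (black bars, n = 3, or 4 for LMPP and GMP GFP-). S100a8 averaged 10.86 in PreMegE and 11.98 in GMP GFP-, while Mpo averaged 9.46 in PreMegE and 13.36 in GMP GFP-.

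Reporter-negative cells of both gates were compared for the step from PreGM to GMP. Gata1 did not differ detectably (-0.32, 95% interval -0.68 to 0.04, adjusted p = 0.710). Granule genes of late neutrophil differentiation were higher in GMP GFP-: Chil3 by 3.23 (SE 0.44, adjusted p = 8.57e-05), the cathelicidin gene Camp by 3.13 (SE 0.45, adjusted p = 2.12e-04) and Ltf by 3.12 (SE 0.56, adjusted p = 0.00269). Ngp was higher by 3.41 (SE 0.75, adjusted p = 0.0188) and S100a8 with an 8.03-fold difference (adjusted p = 0.00572). The GMP GFP- arrays differed in this: the mean of 12 late neutrophil genes was 8.72, 9.37, 10.43 and 10.42 in arrays 1 to 4, against 7.20 to 7.70 in PreGM GFP-. The guanine deaminase gene Gda was higher by 3.22 (SE 0.22, adjusted p = 2.94e-09). Lower in GMP GFP- were Dntt, by 4.54 (SE 0.20, adjusted p = 1.39e-12), the angiopoietin gene Angpt1 by 3.03 (SE 0.29, adjusted p = 9.31e-07), Ctla2a by 2.81, Flt3 by 2.69, Rnase6 by 2.64 and H2-Aa by 2.60. Limma called 183 genes higher and 94 lower. Neutrophil granule genes rose in 16 of 27 with 0 lowered (24 and 0 adjusted over the list alone, camera adjusted p = 8.34e-54). Lymphoid priming genes fell in 5 of 21 with 0 raised (1 and 10 adjusted over the list alone, camera adjusted p = 5.55e-12). B lymphoid genes fell in 2 of 22 with 0 raised (0 and 11 adjusted over the list alone, camera adjusted p = 5.19e-14). T and NK lymphoid genes fell in 3 of 22 with 0 raised (1 and 5 adjusted over the list alone, camera adjusted p = 3.59e-06). This fall rests mostly on PreGM GFP- arrays 1 and 2. As mean deviations from each gene's overall mean, PreGM GFP- arrays 1 to 3 had 0.37, 0.19 and -0.03, and GMP GFP- arrays -0.19 to -0.07. Dendritic cell genes fell in 3 of 17 with 0 raised (0 and 5 adjusted over the list alone, camera adjusted p = 6.83e-07). Stem cell genes fell in 3 of 28 with 0 raised (0 and 5 adjusted over the list alone, camera adjusted p = 4.40e-04), among them Meis1 at -1.71. These 6 calls held with an estimated correlation, the weakest being dendritic cell (adjusted p = 0.0183 with an estimated correlation). The granulocyte factor gene Cebpe rose by 1.86 and the gate's own Fcgr3 by 2.04. In PreGM GFP- the mean of Gda, and in GMP GFP- those of Ctla2a, Dntt, Gata1 and H2-Aa, lay below the median signal, so these differences are not exact.

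Other lists in this step were weaker. Heme synthesis genes passed with 1 of 11 higher, Cpox at 1.14 (camera adjusted p = 0.0157), a call lost without PreGM GFP- array 2 or 3 (adjusted p = 0.0630 and 0.0575). Monocyte and macrophage genes were split, with 2 of 22 higher and 1 lower (camera adjusted p = 0.0221, adjusted p = 0.333 with an estimated correlation), Cybb at 2.92 and Ctss at -1.04 among them. G2 and M phase (camera adjusted p = 4.03e-07, adjusted p = 0.178 with an estimated correlation) and S phase genes (camera adjusted p = 1.53e-04, adjusted p = 0.156 with an estimated correlation) lost their list calls. Interferon response (camera adjusted p = 0.00625, adjusted p = 0.123 with an estimated correlation) and fate regulator genes (camera adjusted p = 0.0205, adjusted p = 0.156 with an estimated correlation) lost theirs. The count of higher genes was 105 without PreGM GFP- array 2, and that of lower genes 60 without GMP GFP- array 1 and 58 without PreGM GFP- array 1. The call of Ngp was lost without GMP GFP- array 3 or 4 or PreGM GFP- array 1 or 2 (adjusted p up to 0.0946), and that of S100a8 without PreGM GFP- array 1 (adjusted p = 0.0565).

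Between the reporter-positive fractions of the same gates, Gata1 differed by -0.40 (95% interval -0.78 to -0.01, adjusted p = 0.648). GMP GFP+ exceeded PreGM GFP+ most in Prg2, by 5.67 (SE 0.49, adjusted p = 1.19e-07), Ear6 by 4.85 (SE 0.29, adjusted p = 2.40e-10), the basophil protease gene Mcpt8 by 4.77 (SE 0.38, adjusted p = 4.77e-08), Prg3 by 4.70, Gzmb by 4.20 and Rnase12 by 4.03. Lower in GMP GFP+ were Mfsd2b, by 2.53 (SE 0.15, adjusted p = 2.40e-10), Plxnc1 by 1.93, the urea transporter gene Slc14a1 by 1.93, Zg16 by 1.93, Aqp9 by 1.88 and Aqp1 by 1.79. Limma called 158 genes higher and 45 lower. Mast cell and basophil genes rose in 13 of 24 with 0 lowered (17 and 0 adjusted over the list alone, camera adjusted p = 2.06e-43). Eosinophil genes rose in 6 of 14 with 0 lowered (9 and 0 adjusted over the list alone, camera adjusted p = 6.93e-29). Neutrophil granule genes rose in 8 of 27 with 0 lowered (10 and 0 adjusted over the list alone, camera adjusted p = 9.20e-17), with Ctsg at 2.76, Ms4a3 at 2.60 and Elane at 1.76. Erythroid genes fell in 4 of 21 with 0 raised (0 and 6 adjusted over the list alone, camera adjusted p = 5.96e-11). Megakaryocyte genes fell in 2 of 20 with 0 raised (0 and 4 adjusted over the list alone, camera adjusted p = 0.00211, adjusted p = 0.0396 with an estimated correlation). Stem cell genes were lower as a list with 0 of 28 called (camera adjusted p = 0.00598, adjusted p = 0.0482 with an estimated correlation). Monocyte and macrophage genes were higher in 2 of 22, Ms4a6c at 3.71 and Cx3cr1 at 1.28, and their list call (camera adjusted p = 6.60e-06) was lost with an estimated correlation (adjusted p = 0.0902). The S phase (camera adjusted p = 0.00483, adjusted p = 0.35 with an estimated correlation) list lost its call as well. The interferon response (camera adjusted p = 0.0269, adjusted p = 0.231 with an estimated correlation) and immediate early and stress lists (camera adjusted p = 0.0404, adjusted p = 0.485 with an estimated correlation) lost theirs too. Id2 was higher by 3.62, Runx1 by 0.98 and Cebpa by 0.86. Without PreGM GFP+ array 2, 105 genes were higher, without GMP GFP+ array 1 24 and without PreGM GFP+ array 3 25 were lower, and the call of Slc14a1 was lost without GMP GFP+ array 1 (adjusted p = 0.0715). In PreGM GFP+ the means of Ear6, Id2, Ms4a6c and Prg3, and in GMP GFP+ that of Zg16, lay below the median signal, so these differences are not exact.

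**Figure D5:**
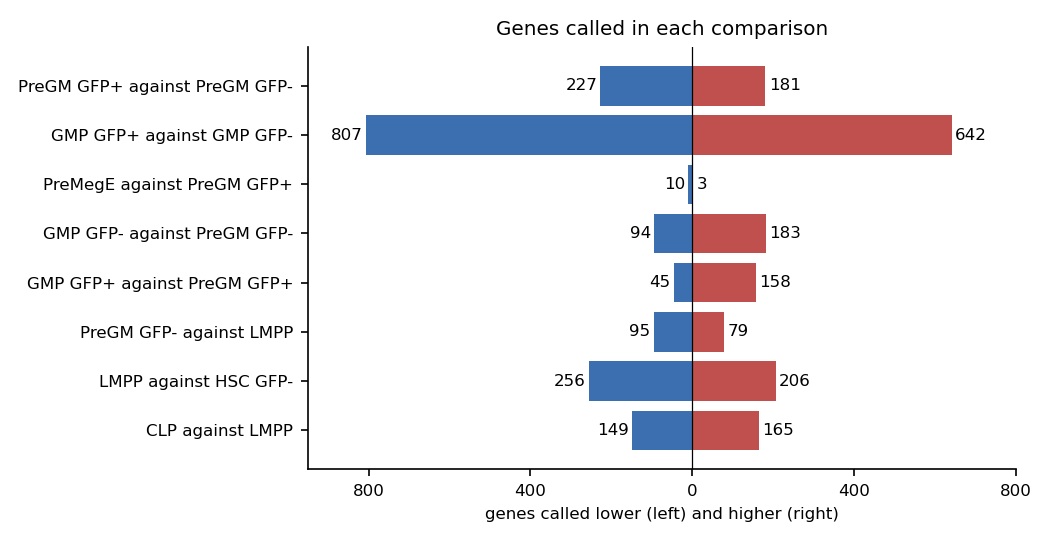
Number of genes called lower (blue, left) and higher (red, right) by limma in the first-named group of each of 8 comparisons (vertical axis). The GMP reporter comparison called 807 lower and 642 higher, and PreMegE against PreGM GFP+ 10 lower and 3 higher.

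PreGM GFP- cells were also set against LMPP, which are reporter-negative and Flt3-high. Gata1 did not differ detectably (0.17, 95% interval -0.19 to 0.53, adjusted p = 0.918). Ms4a3, a gene of granulocyte-monocyte progenitors, was higher in PreGM GFP- by 3.69 (SE 0.27, adjusted p = 6.93e-08), F13a1 by 3.67 (SE 0.39, adjusted p = 7.50e-06), Ly86 by 3.37 (SE 0.32, adjusted p = 2.22e-06), S100a8 by 3.01, Cpa3 by 2.83 and Ctsg by 2.74. Lower in PreGM GFP- were Stxbp4, by 2.42 (-1.72 as the mean of its 2 probe sets), Tspan6 by 2.26, Tnip3 by 2.21, Cd33 by 2.20, Vldlr by 2.12 and Wfdc17 by 2.07. Limma called 79 genes higher and 95 lower. Neutrophil granule genes rose in 7 of 27 with 0 lowered (10 and 1 adjusted over the list alone, camera adjusted p = 1.87e-13) and monocyte and macrophage genes in 5 of 22 with 0 lowered (13 and 0 adjusted over the list alone, camera adjusted p = 1.94e-12). Lymphoid priming genes fell in 6 of 21 with 0 raised (0 and 13 adjusted over the list alone, camera adjusted p = 1.59e-17), with Flt3 at -1.41 and Dntt at -1.26. Interferon response genes fell in 5 of 21 with 0 raised (0 and 10 adjusted over the list alone, camera adjusted p = 5.86e-15), among them Rtp4 at -1.58 and Oasl2 at -1.23. Stem cell genes fell in 2 of 28 with 0 raised (0 and 6 adjusted over the list alone, camera adjusted p = 4.07e-05), with Hlf at -1.70. These 5 calls held with an estimated correlation, the weakest being monocyte and macrophage (adjusted p = 0.010 with an estimated correlation). In LMPP the means of Cpa3, F13a1, Gata1, Hdc, Ms4a3 and S100a8, and in PreGM GFP- those of Cd33, Tnip3 and Tspan6, lay below the median signal, so these differences are not exact.

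In the mast cell and basophil list 4 of 24 genes were higher in PreGM GFP- than in LMPP, Cpa3, Mcpt8 at 2.04, Slc18a2 at 1.42 and Hdc at 1.03 (camera adjusted p = 0.0224), a call lost without PreGM GFP- array 1 or 2 (adjusted p = 0.0524 and 0.0658). The megakaryocyte (camera adjusted p = 0.00965, adjusted p = 0.0671 with an estimated correlation) and S phase (camera adjusted p = 3.32e-04, adjusted p = 0.192 with an estimated correlation) lists lost their calls. So did the B lymphoid (camera adjusted p = 0.0226, adjusted p = 0.321 with an estimated correlation), T and NK lymphoid (camera adjusted p = 0.0224, adjusted p = 0.146 with an estimated correlation) and dendritic cell lists (camera adjusted p = 0.0433, adjusted p = 0.331 with an estimated correlation). The counts of genes between PreGM GFP- and LMPP were 49 higher without PreGM GFP- array 1, and 59, 50, 45 and 59 lower without LMPP array 1, LMPP array 3, PreGM GFP- array 2 and PreGM GFP- array 3. The calls of S100a8 and Tspan6 were lost without PreGM GFP- array 2 (adjusted p = 0.0761 and 0.0980), that of Tspan6 also without PreGM GFP- array 3 (adjusted p = 0.0529).

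LMPP were compared with HSC GFP- for the first step out of the stem cell gate. Gata1, with both means below the median signal, did not differ detectably (0.25, 95% interval -0.11 to 0.61, adjusted p = 0.644). Dntt was higher in LMPP by 5.78 (SE 0.20, adjusted p = 8.27e-15) and Wfdc17 by 3.68 (SE 0.37, adjusted p = 1.93e-06), followed by Atp8b4 at 3.39, Satb1 at 3.34, Flt3, the marker of the gate, at 3.25 and Cd52 at 2.90. Lower in LMPP were Plxdc2, by 3.31 (SE 0.24, adjusted p = 1.15e-08), the aldehyde dehydrogenase gene Aldh1a1 by 3.03 (SE 0.40, adjusted p = 5.86e-05), Slc18a2 by 2.77, Prkg1 by 2.41, Myct1 by 2.38 and Gng11 by 2.30. Limma called 206 genes higher and 256 lower. Stem cell genes fell in 19 of 28 with 0 raised (0 and 26 adjusted over the list alone, camera adjusted p = 3.44e-39), among them Slamf1, the CD150 gene that the gates select on, at -2.25 and the angiopoietin receptor gene Tek at -1.81. Megakaryocyte genes fell in 7 of 20 with 0 raised (0 and 11 adjusted over the list alone, camera adjusted p = 1.40e-10), with the platelet factor gene Pf4 at -2.09. Lymphoid priming genes rose in 6 of 21 with 0 lowered (14 and 1 adjusted over the list alone, camera adjusted p = 3.03e-22). G2 and M phase genes rose in 6 of 24 with 0 lowered (23 and 0 adjusted over the list alone, camera adjusted p = 4.33e-25). S phase genes rose in 3 of 28 with 0 lowered (10 and 0 adjusted over the list alone, camera adjusted p = 6.37e-11). These 5 calls held with an estimated correlation, the weakest being S phase (adjusted p = 0.0238 with an estimated correlation). B lymphoid (camera adjusted p = 1.66e-04, adjusted p = 0.0930 with an estimated correlation) and neutrophil granule genes (camera adjusted p = 0.00150, adjusted p = 0.241 with an estimated correlation) lost their list calls. Mpo was higher by 2.55, and the late neutrophil gene S100a9 stood at 10.1 in LMPP array 2. Without LMPP array 3 the count of higher genes was 130. In HSC GFP- the means of Atp8b4, Dntt and Wfdc17, and in LMPP those of Aldh1a1, Gng11, Pf4, Plxdc2, Prkg1, Slamf1 and Tek, lay below the median signal, so these differences are not exact.

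CLP were compared with LMPP for the lymphoid step. Gata1, with both means below the median signal, did not differ detectably (-0.15, 95% interval -0.52 to 0.21, adjusted p = 0.870). The recombinase gene Rag1 was higher in CLP by 4.32 (SE 0.23, adjusted p = 3.93e-11), Ly86 by 3.67 (SE 0.32, adjusted p = 1.07e-07) and Il7r, the interleukin 7 receptor gene of the gate itself, by 3.65 (SE 0.27, adjusted p = 1.39e-08). Ly6d was higher by 3.42 (SE 0.18, adjusted p = 3.93e-11), the adaptor gene Blnk by 3.36 and the surrogate light chain gene Vpreb1 by 3.84 (SE 0.92, adjusted p = 0.0309). Lower in CLP were Atxn1, by 4.75 (-2.71 as the mean of its 2 probe sets), Cd63 by 3.77, Stxbp4 by 3.70 (-2.44 as the mean of its 2 probe sets), Car2 by 3.20, Vldlr by 3.17 and the stem cell factor gene Hlf by 3.07. Limma called 165 genes higher and 149 lower. B lymphoid genes rose in 16 of 22 with 0 lowered (18 and 0 adjusted over the list alone, camera adjusted p = 2.82e-44), with the B cell factor genes Ebf1 at 3.23 and Pax5 at 1.36. Dendritic cell genes rose in 5 of 17 with 0 lowered (8 and 0 adjusted over the list alone, camera adjusted p = 2.01e-11), led by the plasmacytoid gene Siglech at 3.14. Monocyte and macrophage genes rose in 8 of 22 with 0 lowered (13 and 2 adjusted over the list alone, camera adjusted p = 2.01e-11), with Irf8 at 2.82. The dendritic and monocyte rises rest mostly on 2 of 3 arrays: as mean deviations from each gene's overall mean, CLP arrays 1, 2 and 3 had 1.12, 1.0 and 0.19 for dendritic and 1.21, 1.16 and 0.06 for monocyte and macrophage genes, with LMPP arrays at most 0.01 and -0.11. B lymphoid genes had 1.52, 1.39 and 1.96 in the same arrays. Interferon response genes fell in 5 of 21 with 0 raised (0 and 9 adjusted over the list alone, camera adjusted p = 3.49e-13) and stem cell genes in 6 of 28 with 0 raised (0 and 10 adjusted over the list alone, camera adjusted p = 6.48e-11). These 5 calls held with an estimated correlation, the weakest being monocyte and macrophage (adjusted p = 0.0143 with an estimated correlation). Neutrophil granule (camera adjusted p = 0.00122, adjusted p = 0.211 with an estimated correlation) and G2 and M phase (camera adjusted p = 2.01e-11, adjusted p = 0.111 with an estimated correlation) lists lost their calls. So did the S phase (camera adjusted p = 1.84e-04, adjusted p = 0.198 with an estimated correlation) and fate regulator lists (camera adjusted p = 0.00328, adjusted p = 0.104 with an estimated correlation). Without CLP array 2 the counts were 108 higher and 91 lower, and the call of Vpreb1 was lost without any of 5 of the 7 arrays (adjusted p up to 0.152 without CLP array 3). In LMPP the means of Ebf1, Il7r, Rag1 and Siglech, and in CLP those of Atxn1, Car2, Cd63, Stxbp4 and Vldlr, lay below the median signal, so these differences are not exact.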

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

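The tests of these 3 patterns were chosen only after the results were seen, except the chance splits. Late neutrophil transcripts were high in PreMegE. The mean of 12 late neutrophil genes was 8.69 ± 0.47 (SD, n = 3) in PreMegE, against 6.35 ± 0.10 in HSC GFP- (difference 2.34, SE 0.28) and 7.19 ± 0.74 in PreGM GFP+ (1.5, SE 0.50), and PreGM GFP+ exceeded HSC GFP- by 0.83 (SE 0.43). Shares of unlogged signal argue against granulocyte-fated progenitors with the profile of GMP GFP-. The late genes would need a median 30.7% of GMP GFP- signal (33.7% over HSC GFP- in place of PreGM GFP+). In PreMegE the early promyelocyte genes Mpo, Elane, Prtn3, Ctsg and Ms4a3 allow 2.86% to 8.16%. The gap was 3.76 times (2.52 to 4.74 with 1 array left out). These shares take signal as proportional to RNA, which was not shown for late genes below the median signal in HSC GFP- or PreGM GFP+. RNA or cells from mature neutrophils, which the lineage-negative sort should remove, or granulocytic cells past the promyelocyte stage could cause the late transcripts. Of the 12 genes 8 (66.7%) lay over 1 log2 unit above HSC GFP-, and with a bar of 75% the test cannot tell.

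Mast cell, basophil and eosinophil genes, with erythroid genes, rose in GMP GFP+. PreGM GFP+ cells carried into that gate cannot make the first part, as 17 of 26 called genes (65.4%) were higher in GMP GFP+ than in PreGM GFP+ by test. For the 14 called erythroid genes, the share of PreGM GFP+ signal needed ran from 9.38% for Mfsd2b to 132% for Epb42, a ratio of 14.1 (13.7 to 30.3 with 1 array left out), where 1 contaminating population would need 1 share. Mature eosinophils, basophils or mast cells may add to it: their 9 measured markers averaged 6.46 in GMP GFP+, 0.45 (SE 0.03) above GMP GFP-, but below the median signal, so the test cannot tell.

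More genes were called by reporter in GMP (1449) than in PreGM (408). The additional GMP GFP- array does not account for the whole gap. With 1 GMP GFP- array left out the counts fell to 1057, 953, 1001 and 1317, all still above 408. The fall leaves open that it accounts for a part. The spread of PreGM GFP- array 2 alone does not account for the whole gap either, with 466 genes called in PreGM without it. Arrays 1 and 3 of that group also had low precision weights (0.383 and 0.483, against 0.752 to 1.73 in GMP GFP-). Leaving out array 2 therefore cannot exclude a larger spread of PreGM GFP- as a group. With the spread taken from the groups compared alone the counts lay further apart, at 89 higher and 128 lower in PreGM and 588 higher and 1061 lower in GMP. The cause was not tested further.

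The same arrays were also divided into groups in other ways, to see how many genes other divisions would call. These divisions can keep arrays of a real group together, and they put the real difference into the spread, which holds their counts down. A low count in them is thus partly built into the test. In GMP 1 of 35 splits, the real one, called as many genes as the 1449 called (highest other 389), in GMP GFP- against PreGM GFP- 1 of 35 (277, highest other 63), in PreGM GFP- against LMPP 1 of 35 (174, highest other 53), in LMPP against HSC GFP- 1 of 35 (462, highest other 113) and in CLP against LMPP 1 of 35 (314, highest other 64). The F test had 1 of 100 (3036, highest other 7). For the difference of the reporter effects 4 of 100 splits, the real one included, called 140 genes or more (highest other 960); of the other 3, 1 kept the real GMP groups and 2 the real PreGM groups, so each carried a whole reporter effect. With 3 against 3 arrays 10 splits are too few for a share under 0.05: the real and highest other counts were 408 and 1 in PreGM, 13 and 2 for PreMegE against PreGM GFP+, and 203 and 2 for GMP GFP+ against PreGM GFP+, with 1 split, the real one, reaching the count in each.

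Single arrays stood apart in 10 of 109 group and gene or list combinations by Dixon's ratio at the 5% level, where about 1 in 20 would by chance. In GMP GFP- these were Clec4a2 (ratio 0.834), Clec5a (0.871), Fcer1a (0.838) and the fate regulators list (0.929). In LMPP they were Cd33 (0.837), Il7r (0.883), Prkg1 (0.886), Satb1 (0.873), Tspan6 (0.835) and the stem cell list (0.949). The ratio takes no account of size. The stem cell list in LMPP ran only from 7.003 to 7.036, and Fcer1a in GMP GFP-, below the median signal, from 4.18 to 4.46. Il7r in LMPP ran further, from 5.55 to 6.60. No cause was tested for these arrays.

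The reporter effect differed between PreGM and GMP in 140 genes. The named ones, as the log2 effect in PreGM minus that in GMP, were Camp 3.08, Chil3 2.76, Mfsd2b 2.64, Ly6a2 2.51, Clec4a2 2.44, Stom 2.32, Clec5a 2.16 and Ces2g 1.86 in 1 direction. In the other direction they were Prg2 -5.25, Id2 -4.98, Ear6 -4.95, Dntt -4.50, Mcpt8 -4.22, Ms4a6c -4.22, Gzmb -4.17, Prg3 -3.95, Cd53 -3.75, Rnase12 -3.01, Flt3 -2.97, Il6 -2.94, Emb -2.87, Fcer1a -2.85, Milr1 -2.81, Slc18a2 -2.32, Clec12a -2.18 and Ms4a2 -1.65. The list medians were erythroid 0.10, neutrophil granule 0.68, mast cell and basophil -0.94, eosinophil -0.59, lymphoid priming -0.43, B lymphoid -0.40, dendritic cell -0.29 and T and NK lymphoid -0.29.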

How the results depend on the processing

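The number of arrays, 3 or 4 per group, limits what these counts can show, and signals near background limit genes below the median signal. In 138 results for named genes, 131 of them past the threshold, 112 of 2595 alternative values lost the call, and 108 results never lost it. Where the main or the alternative test passed, 0 values turned direction. Apart from Gata1 and the difference of the reporter effects, these genes were chosen as the largest called differences without overlap of arrays. Leaving out an array could therefore not turn their direction, and the choice favours calls that hold. Where a count moved, the cause was not tested. As a replicate block, the arrays' numbers left 1 gene higher in PreMegE against PreGM GFP+ in place of 3 and moved no other count by over 1.5 times. Same-numbered arrays deviated together little (mean r 0.027, from -0.263 to 0.325, 18 of 85 pairs over 0.1). For arrays of other numbers the mean r was -0.0099, with 26 of 210 pairs over 0.1. Yet in 13 of 24 checks an array correlated best with its own number in the group it was compared with, where 7.25 would by chance. GMP GFP+ arrays entered these checks in more than 1 comparison. The Y-linked mean ranked arrays 1 to 3 alike in 6 of 8 groups, with another shared order in HSC GFP- and PreMegE. Numbers may thus mark shared animals or sorts, which the labels do not say, and were not taken to pair samples. A block in those 6 groups alone, chosen after seeing the data, moved no count by over 1.5 times (212 and 288 for the PreGM reporter). That block did not cover PreMegE against PreGM GFP+ or LMPP against HSC GFP-. If numbers have another meaning in HSC GFP- and PreMegE, the block over all groups does not test pairing in these comparisons.

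Counts are given as higher and lower in the first-named group. With arrays weighted by precision they were 93 and 120 for the PreGM reporter, 1249 and 1550 for the GMP reporter, 65 and 34 for GMP GFP- against PreGM GFP-, 19 and 27 for PreGM GFP- against LMPP, 410 and 432 for LMPP against HSC GFP-, 301 and 280 for CLP against LMPP, and 4649 in the F test. In the same setting 127 were lower in GMP GFP+ against PreGM GFP+ and 17 in PreMegE. In the groups compared alone they were 89 and 128 for the PreGM reporter, 109 higher for GMP GFP- against PreGM GFP-, 95 and 21 for GMP GFP+ against PreGM GFP+, 33 and 33 for PreGM GFP- against LMPP, 107 and 121 for LMPP against HSC GFP-, 69 and 96 for CLP against LMPP, and 0 and 0 for PreMegE. At 2-fold or more they were 112 higher for the PreGM reporter, 204 and 268 for the GMP reporter, 111 and 54, 47 and 62, 91 and 114, and 92 and 96 for GMP GFP- against PreGM GFP-, PreGM GFP- against LMPP, LMPP against HSC GFP- and CLP against LMPP, and 25 lower for GMP GFP+ against PreGM GFP+. Among genes above the median level 371 were higher for the GMP reporter, 105 lower in LMPP, 89 higher in CLP, and 23 and 64 differed in effect. Without the widest array of each of PreGM GFP-, PreMegE and HSC GFP-, 369 were lower for the PreGM reporter, 119 higher for GMP GFP- against PreGM GFP- and 60 lower for PreGM GFP- against LMPP. With the residual component as a covariate 59 differed towards PreGM and 149 were lower for PreGM GFP- against LMPP. PreMegE had 1 gene higher with arrays centred on their medians or the Y-linked covariate, 0 with cyclic loess, and 0 higher and 6 lower with every probe set.

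With 1 array left out in turn, the counts ran from 118 to 168 higher and 134 to 298 lower for the PreGM reporter, 320 to 624 and 489 to 748 for the GMP reporter, 30 to 59 and 67 to 98 for the difference of the effects, 0 to 2 and 5 to 10 for PreMegE against PreGM GFP+, 105 to 175 and 58 to 81 for GMP GFP- against PreGM GFP-, 105 to 134 and 24 to 37 for GMP GFP+ against PreGM GFP+, 49 to 84 and 45 to 105 for PreGM GFP- against LMPP, 130 to 216 higher for LMPP against HSC GFP-, and 108 to 210 and 91 to 167 for CLP against LMPP. The correlation of the reporter effects ran from 0.389 to 0.554. List medians turned direction in 6 cases where the list test passed with all arrays or with the array left out. Turns where neither test passed were not counted. Ranges were -0.0148 to 0.135 for B lymphoid genes in LMPP against HSC GFP- and -0.0205 to 0.0494 for fate regulators by reporter in PreGM. They were -0.104 to 0.290 for G2 and M phase genes in PreMegE against PreGM GFP+. For immediate early and stress genes in GMP GFP+ against PreGM GFP+ the range was -0.132 to 0.0407. For mast cell and basophil genes in PreGM GFP- against LMPP it was -0.0338 to 0.120, and for neutrophil granule genes in CLP against LMPP -0.0997 to 0.00464.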

Other observations

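Among the genes that do not depend on a gate's own antigens, reporter-positive cells of PreGM and GMP shared a rise of Gata2 (1.80 and 2.36) and Gfi1b (1.10 and 1.10) and a fall of Irf8 (-1.95 and -2.05). Cd34 fell by 2.21 in PreGM GFP+ and 0.91 in GMP GFP+, while Kit was not called in either gate (0.64 and 0.64). Meis1, a stem cell regulator, rose by 1.61 in GMP GFP+.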
